A study of Mus musculus with 34 samples.

How the data were processed

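Bulk RNA-seq was carried out on pancreatic islets of mice labelled RIP-DTR HTZ, in which the rat insulin promoter drives a receptor for diphtheria toxin (DT). Per the labels, the mice received DT, streptozotocin (STZ, a toxin taken up by beta cells) at 75 mg/kg or neither, and were sampled 5 days (5 DPA), 30 days (30 DPA) or 10 weeks later, at 10 weeks on a diet labelled SD or HFD. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit and libraries were made with the QIAseq stranded mRNA kit. The labels name the mouse assembly mm10. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here.

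The deposited table holds, per the file headers, total counts of reads per gene for each of 34 libraries, with no normalization, and these counts were the input of every test. The authors' RPKM and TPM values stand beside the counts in the same table and were not used. A further deposited column per library is headed CPM but sums to between 0.784 and 2.106 times the sum that CPM has, so that it is a score with an extra scaling factor per library that no source explains, and it was not used either. Each column was assigned to its library by the library number in the labels, and 0 columns belonged to other samples. The table lists 48709 genes, none without a name, of which 48349 identifiers (99.26%) were found in GENCODE release M21 on GRCm38, the assembly also called mm10. Coordinates and gene types come from that annotation. Total counts ranged from 11083117 to 18918348 per library.

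The labels placed 33 libraries in 9 groups of 3 or 4. The remaining library is titled as a CTRL HFD replicate while its treatment label is DT, so it entered no comparison. No label says that replicates come from separate animals, and p-values therefore measure the spread between these samples. Within every group each pair of libraries differed by more than counting noise (the smallest chi-square per degree of freedom was 26.06), and none was counted as a duplicate.

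Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) by group, with a count minimum of 10 and a total minimum of 15, which left 17616 genes. TMM scaling and 1 quasi-likelihood fit with robust shrinkage over all 33 libraries were used, with group as the only factor. The 15 comparisons were contrasts of that fit. Adjusted p-values are those of edgeR's quasi-likelihood F test with the Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p below 0.05. Standard errors (SE) are on the log2 scale. The prior degrees of freedom were between 1.63 and 3.11, so each gene's spread was estimated largely from its own values. CPM values are relative to the TMM-scaled library size, and a list score is the mean log2 CPM of a list's tested members with a prior count of 2.

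Gene lists, 29 in number, for the cell types an islet preparation can hold, for the cell cycle and for stress, secretion and metabolism were fixed together with the comparisons, the tests and most of the other settings before the data were examined. Each list was tested in each comparison with camera (limma 3.58.1) at a preset correlation of 0.01, and the 435 p-values were adjusted together. Camera compares a list with all other genes. Of these tests 163 passed with the preset correlation and 0 with a correlation estimated per list, while 35 passed with fry, which tests whether a list's genes move on balance one way. Every list call below therefore rests on the preset correlation, and the estimated one is given beside it.

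The genes named were chosen by a rule fixed at the same time. It takes Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Slc2a2, Mki67, Top2a and Cdkn1a in each comparison, up to 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 (leaving out symbols that begin with Gm and digits, end in Rik, contain -ps or begin with mt-), and the 3 list members with the smallest adjusted p below 0.05 per list. Genes outside the rule are said to be so, and not every gene the rule names is reported here. Reads of genes with near-identical copies, such as Rps2, the Reg, Saa and Gsta families, Hspa1a and the histone genes, could be split between copies by the counting, and their values are uncertain for that reason.

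Data simulated once per comparison had 200 of 17616 genes changed. Over 15 comparisons edgeR recovered 12.6% to 35.1% of 2-fold and 51.7% to 79.8% of 4-fold changes. Of its calls 1.05% to 9.38% were false. For DESeq2, in 3 comparisons, 14.16% to 20.83% were false. These are not error rates of the calls below, where libraries also varied in RNA of other tissues. The other settings fixed beforehand were DESeq2 size factors, no low-count filter and a stricter one (at least 1 CPM in 3 libraries and 50 counts in all), hormone genes left out before scaling, the acinar score as a covariate, the replicate number as a block, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, and leaving out each library in turn. After seeing the data, fits with lymphocyte and enterocyte scores as covariates and fits without the 8 libraries whose enterocyte markers summed to more than 500 CPM were added.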

Results

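Gene expression was measured in islets of untreated mice and of mice given a toxin to ablate part of their beta cells, to describe the molecular response over time and on 2 diets. DT was given to mice whose insulin-producing cells carry the toxin receptor, and islets were taken 5 days later (DT 5 DPA, n = 4) or 30 days later (DT 30 DPA, n = 4). They were set against untreated mice with no time or diet in their labels (CTRL, n = 3). A 10-week series compared untreated mice (CTRL SD, n = 3, and CTRL HFD, n = 4), DT mice (DT SD, n = 4, and DT HFD, n = 3) and mice given 75 mg/kg STZ (STZ SD, n = 4, and STZ HFD, n = 4). The first principal component of log2 CPM took 28.56% of the variance, the next 16.14%.

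Insulin transcripts were the most abundant in nearly all libraries. Ins2 ranked first in each library except CTRL HFD replicate 4 and DT HFD replicate 2, where Gcg (glucagon) did, and STZ HFD replicate 4, where the acinar amylase Amy2a1 did. Ins2 stood at 69364 ± 34769 CPM (SD, n = 3) in CTRL, 55393 ± 26100 (n = 4) at 5 DPA and 139280 ± 53186 (n = 4) at 30 DPA. On SD at 10 weeks it was 114650 ± 7760 (n = 3) in CTRL, 158440 ± 6951 (n = 4) after DT and 99244 ± 41390 (n = 4) after STZ. On HFD the values were 70664 ± 36626 (n = 4), 52951 ± 29571 (n = 3) and 77436 ± 33502 (n = 4). Ins1, the other insulin gene of the mouse, followed the same order between groups at lower levels, from 20618 ± 11322 CPM (n = 3) in DT HFD to 68858 ± 4638 (n = 4) in DT SD.

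Hbegf (chromosome 18, 36504927 to 36515805) encodes the growth factor precursor HB-EGF, whose primate form serves as the toxin receptor in such mice. Whether reads of the transgene were counted under Hbegf is not given in the sources used here. Hbegf ranged from 23.5 to 114.9 CPM (median 77.5) in the 10 untreated libraries of the groups and from 3.72 to 22.0 CPM (median 13.1) in the 15 DT libraries. The 8 STZ libraries ranged from 5.62 to 408.4 CPM, with a median of 13.7. It was chosen after its values were seen and passed the edgeR test in no comparison, the smallest adjusted p being 0.0606 for STZ against DT on HFD (log2 fold change 4.10, SE 0.99). That difference was carried by STZ HFD replicate 1 (408.4 CPM), while the other 3 were at 5.62 to 14.9 CPM against 3.72 to 9.79 in DT HFD.

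**Figure D1:**
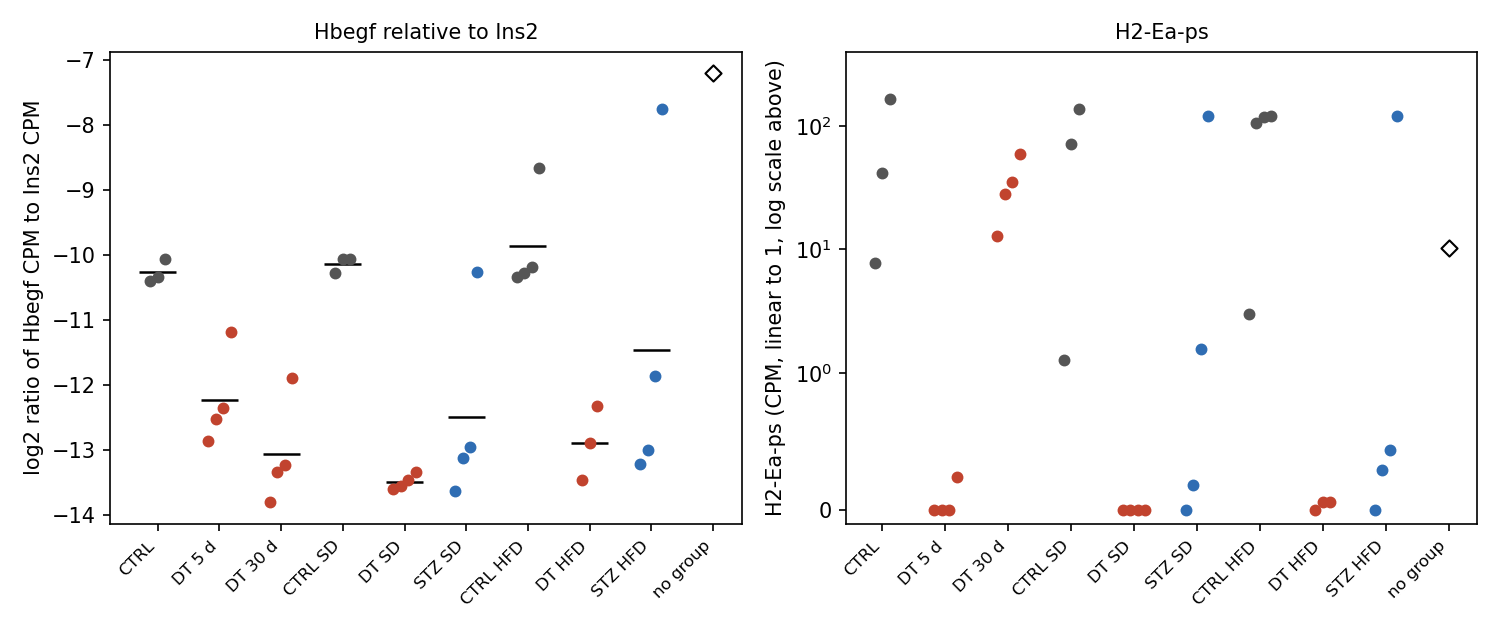
Left, log2 ratio of Hbegf CPM to Ins2 CPM per library by group, with a bar at the group mean; right, CPM of the pseudogene H2-Ea-ps per library (linear to 1, log scale above), with 1 point per library and a diamond for the library in no group. The 15 DT libraries lie below the lowest of the 10 untreated libraries in the ratio (-10.40), and H2-Ea-ps spreads from 0 to 164.3 CPM.

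RNA of neighbouring tissues was present in some libraries. Enterocyte markers such as Apoa1 and Sis summed to 17671 and 11290 CPM in STZ SD replicates 4 and 1 and to 6759 CPM in CTRL replicate 2. They also exceeded 500 CPM in DT 5 DPA replicates 1, 2 and 4, DT 30 DPA replicate 2 and DT HFD replicate 1. Acinar markers took 38.1% of the counts of STZ HFD replicate 4. The lymphocyte score (mean log2 CPM of T and B cell markers) was 6.88 in CTRL replicate 2, 6.57 in STZ HFD replicate 2 and 6.42 in DT HFD replicate 2. Sympathetic neuron genes reached 858 CPM (Dbh) and 382.5 CPM (Th) in DT 30 DPA replicate 2.

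**Figure D2:**
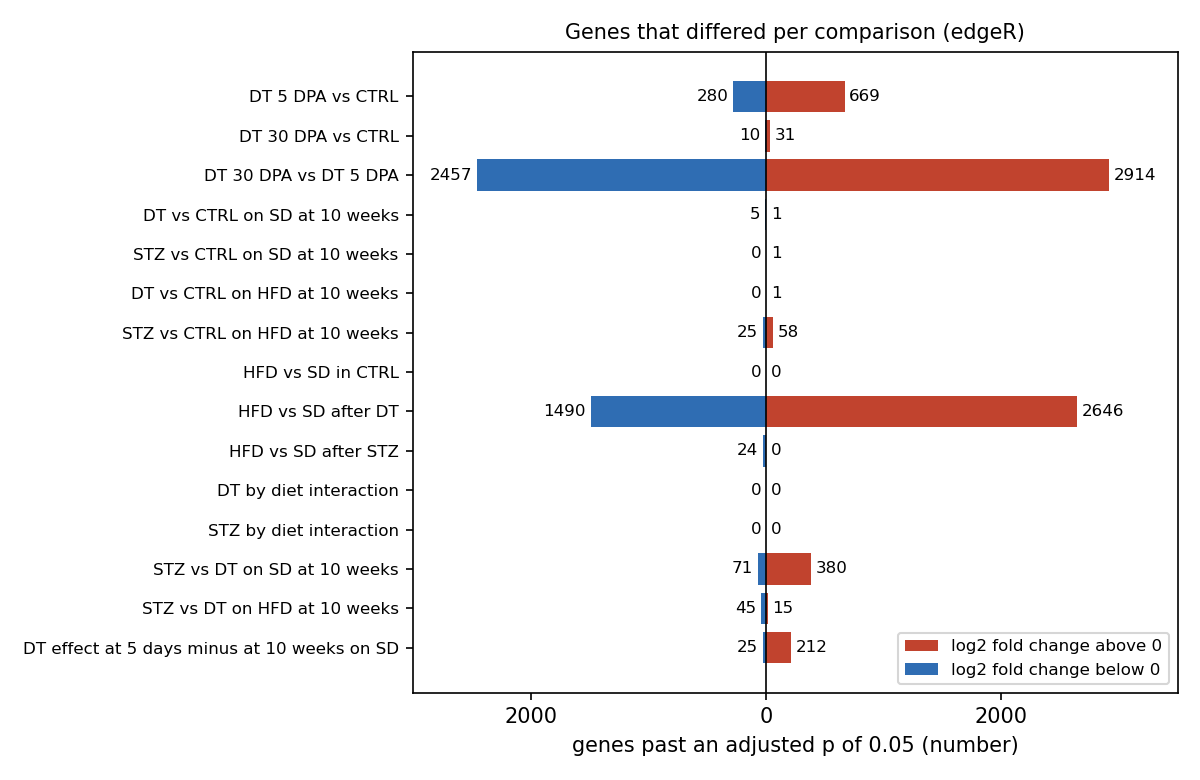
Number of genes called at an adjusted p below 0.05 by edgeR in each of the 15 comparisons, split into log2 fold changes above and below 0. The largest numbers are 5371 for DT 30 DPA against DT 5 DPA and 4136 for HFD against SD after DT, and 3 comparisons have 0.

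At 5 DPA the islets carried far more macrophage and interferon-response transcripts than CTRL islets. Saa3, an acute-phase protein of inflamed tissue, was counted 2, 19 and 28 times in the CTRL libraries and 35837 to 43916 times in the 4 libraries at 5 DPA (log2 fold change 11.42, SE 1.38, adjusted p = 9.83e-06). Acod1, which makes the macrophage metabolite itaconate, rose 169-fold (adjusted p = 2.91e-05). Clec4d, a lectin of myeloid cells, rose 105-fold (adjusted p = 3.57e-05). Adgre1, the macrophage surface protein F4/80, went from 18.6 ± 4.93 CPM (SD, n = 3) to 226.7 ± 51.1 (n = 4), a log2 fold change of 3.61 (SE 0.37, adjusted p = 1.24e-06). Collagen genes of fibroblasts rose too. Col1a1 stood at 127.1 ± 54.5 CPM (n = 3) and 628.3 ± 74.8 (n = 4), and Col3a1 was 5.26-fold higher (adjusted p = 9.88e-06).

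Among the 20 myeloid and MHC class II genes, 13 rose at 5 DPA, and 13 when adjusted over the list alone (median log2 fold change 1.67, camera adjusted p = 1.63e-17, adjusted p = 0.584 with an estimated correlation). C1qa, a complement component of macrophages, rose 3.60-fold. Of the 20 interferon-response genes 13 rose, and 17 adjusted over the list alone (median 1.43, camera adjusted p = 9.74e-18, adjusted p = 0.356 with an estimated correlation). They included Gbp2, a guanylate-binding protein, at 49.0 ± 19.9 CPM (n = 3) in CTRL and 349.8 ± 119.3 (n = 4) at 5 DPA, and the antiviral genes Oasl2 (4.13-fold) and Rsad2 (3.21-fold). Immediate early and heat shock genes rose in 8 of 15 cases, and 10 adjusted over the list alone (median 1.25, camera adjusted p = 1.21e-09, adjusted p = 0.203 with an estimated correlation). Among them were the transcription factor Atf3 (6.16-fold), the phosphatase Dusp1 (3.20-fold) and the chaperone Hspa1a (4.62-fold). The mesenchymal list had 5 of 14 genes higher, and 6 adjusted over the list alone (median 0.72, camera adjusted p = 1.95e-07, adjusted p = 0.584 with an estimated correlation). Glycolysis genes were higher in 3 of 14 cases and in 8 adjusted over the list alone (median 0.76, camera adjusted p = 6.78e-07, adjusted p = 0.743 with an estimated correlation). Pgam1, a glycolytic mutase, rose 1.75-fold. The chaperone and folding genes of the unfolded protein response were higher in 4 of 24 cases and in 7 adjusted over the list alone (median 0.31, camera adjusted p = 5.86e-06, adjusted p = 0.743 with an estimated correlation). Of these Sdf2l1 was 2.06-fold and the disulfide isomerase Pdia6 1.86-fold higher. Hmox1, the heme-degrading enzyme, rose 11.9-fold and the mitochondrial superoxide dismutase Sod2 1.85-fold. With the enterocyte libraries left out, so 1 library at 5 DPA, Pgam1, Sdf2l1, Pdia6, Hmox1 and Sod2 were at 0.66, 0.89, 0.82, 2.47 and 0.66 on the log2 scale and did not pass (adjusted p = 0.0741, 0.118, 0.117, 0.0624 and 0.0994). Prg4 (lubricin), which the delta-cell list holds but which synovial and mesothelial cells are known to make, rose 74.6-fold.

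Cell-cycle lists were higher at 5 DPA as groups, while few of their genes passed singly. All 22 mitosis genes had log2 fold changes above 0 (median 1.13), 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 3.63e-07, adjusted p = 0.775 with an estimated correlation). The proliferation marker Mki67 stood at 35.3 ± 16.1 CPM (SD, n = 3) in CTRL and 90.7 ± 24.2 (n = 4) at 5 DPA, with a log2 fold change of 1.36 (SE 0.62) that did not pass edgeR's test (adjusted p = 0.224). The same held for the topoisomerase Top2a (1.16, SE 0.60, adjusted p = 0.296). All 28 DNA replication genes were above 0 (median 0.78), 2 passed over all genes and 2 adjusted over the list alone (camera adjusted p = 9.79e-08, adjusted p = 0.756 with an estimated correlation). Cdkn1a, the p53 target that encodes the cell-cycle inhibitor p21, rose 4.35-fold (adjusted p = 0.00889). This call ended without CTRL replicate 1 (adjusted p = 0.072) and without CTRL replicate 3 (adjusted p = 0.0643). Of 20 p53 targets 4 rose, and 5 adjusted over the list alone (median 0.25, camera adjusted p = 0.00439, adjusted p = 0.584 with an estimated correlation). They included the cyclin Ccng1 (1.46-fold), at 0.55 on the log2 scale without the libraries with enterocyte RNA, which left 1 library at 5 DPA (adjusted p = 0.0996).

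Beta-cell genes were lower at 5 DPA as a list and in no single gene. Their median was -0.50 over 19 genes, with 0 passing over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.907 with an estimated correlation). The call ended without CTRL replicate 1 (adjusted p = 0.102), CTRL replicate 3 (0.949) or DT 5 DPA replicate 1 (0.517). Ins2 (log2 fold change -0.32, SE 0.55, adjusted p = 0.808), Mafa, a beta-cell transcription factor (-0.30, adjusted p = 0.772), and Slc2a2, the glucose transporter GLUT2 (-0.85, adjusted p = 0.275), did not pass. Nor did Sst, somatostatin of delta cells (-1.90, adjusted p = 0.13), or Ppy, pancreatic polypeptide (-3.01, SE 1.63, adjusted p = 0.322). Ppy stood at 1208 CPM in DT 5 DPA replicate 1 and at 5.60 to 13.3 in the other 3, and without replicate 1 it passed (-8.02, adjusted p = 0.0146). The 6 Reg genes, which encode secreted proteins of injured pancreas, had a median of 2.21 with 0 passing over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00619, adjusted p = 0.756 with an estimated correlation; 0.0507 with the preset correlation without CTRL replicate 1). Lymphocyte genes were lower as a list (median -1.37, 0 of 15 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.902 with an estimated correlation). That call ended without CTRL replicate 1 (0.0832), CTRL replicate 2 (0.716) or DT 5 DPA replicate 3 (0.279). Acinar genes were higher as a list (median 1.31, 0 of 25 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.932 with an estimated correlation), and this ended without CTRL replicate 2 (0.521) or DT 5 DPA replicate 3 (0.306).

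By edgeR 949 genes were called between DT 5 DPA and CTRL, 669 higher and 280 lower. Without CTRL replicate 2 the numbers were 668 and 601, and with the compared groups alone 306 and 14. Each of the 41 genes named by the rule and called had all 4 DT libraries on the called side of the CTRL mean. In all 586 were called without CTRL replicate 1, 451 higher and 135 lower. Without the libraries with enterocyte RNA, which left 1 library at 5 DPA and 2 in CTRL, 329 genes were called, and the lone library is assumed to vary like the others.

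At 30 DPA the genes of secretory granules and exocytosis were above CTRL as a group, and bulk RNA does not show in which cells. All 20 secretory granule and exocytosis genes had log2 fold changes above 0 (median 0.84), of which 0 passed over all genes and 13 adjusted over the list alone (camera adjusted p = 5.26e-11, adjusted p = 0.743 with an estimated correlation). The unfolded protein response list had 3 of 24 genes higher, and 10 adjusted over the list alone (median 0.48, camera adjusted p = 4.51e-07, adjusted p = 0.734 with an estimated correlation). The 3 were the chaperone Hyou1 (2.04-fold), the secreted factor Manf (1.84-fold) and Pdia6 (1.86-fold). For sterol and fatty acid synthesis 1 of 22 genes passed over all genes, the sterol oxidase Msmo1 (2.04-fold). Adjusted over the list alone 14 were higher and 1 lower (median 0.64, camera adjusted p = 5.37e-07, adjusted p = 0.743 with an estimated correlation). Among the called genes that the naming rule admits, the neuropeptide genes Cartpt and Npy rose most. They went from 1.00 ± 0.179 to 19.97 ± 20.8 CPM and from 11.98 ± 4.90 to 167.4 ± 221.0 CPM (SD, n = 3 and 4). Npy stood at 493.5 CPM in DT 30 DPA replicate 2, the library with sympathetic neuron RNA, and at 27.1 to 114.5 CPM in the other 3, and without that library its log2 fold change of 3.80 was 2.29 (adjusted p = 0.145). Cartpt stood at 50.8 CPM in DT 30 DPA replicate 4 and at 6.50 to 14.3 in the other 3, and without replicate 4 its log2 fold change of 4.31 was 3.27 (adjusted p = 0.0697). The early response gene Ier2 (log2 fold change -1.11) and Trp53, which encodes p53 (-0.90), fell.

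Beta-cell markers at 30 DPA were higher than in CTRL as a list, with all 19 above 0 (median 0.83), 0 passing over all genes and 0 adjusted over the list alone (camera adjusted p = 7.88e-07, adjusted p = 0.756 with an estimated correlation). Acinar genes were higher as a list (median 1.98, 0 of 25 over all genes and 0 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.865 with an estimated correlation). Lymphocyte genes (median -1.82, 0 of 15 over all genes, 15 lower adjusted over the list alone, camera adjusted p = 0.000128, adjusted p = 0.798 with an estimated correlation) and myeloid genes (median -0.80, 0 of 20 over all genes, 9 lower adjusted over the list alone, camera adjusted p = 3.38e-05, adjusted p = 0.775 with an estimated correlation) were lower. The lymphocyte score of CTRL replicate 2 was 6.88, and its enterocyte markers summed to 6759 CPM. Without the libraries with enterocyte RNA the lymphocyte and myeloid medians were -0.82 and -0.44 and neither list passed (adjusted p = 0.123 and 0.0879). Mki67 (log2 fold change -0.10, SE 0.60, adjusted p = 0.94) and Cdkn1a (0.16, SE 0.47, adjusted p = 0.861) did not pass.

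Only 41 genes were called between DT 30 DPA and CTRL, 31 higher and 10 lower, although 4465 had an unadjusted p below 0.05. Their adjusted p-values lay between 0.0398 and a value that rounds to 0.05, so small shifts ended or multiplied the calls. By edgeR 0 genes were called without CTRL replicate 1 or 2 or DT 30 DPA replicate 2 or 4. Without DT 30 DPA replicates 1 and 3 and CTRL replicate 3 they were 639, 237 and 4273. The DESeq2 Wald test called 1849 genes, edgeR 0 without the libraries with enterocyte RNA, and 312 with hormone genes left out before scaling, of which 166 were higher and 146 lower.

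Between 5 and 30 days after DT the inflammatory transcripts went down and the endocrine ones up. All 20 interferon-response genes fell (median log2 fold change -2.14, 20 adjusted over the list alone, camera adjusted p = 1.69e-16, adjusted p = 0.408 with an estimated correlation). So did 18 of 20 myeloid genes (median -2.41, 20 adjusted over the list alone, camera adjusted p = 1.57e-17, adjusted p = 0.584 with an estimated correlation). Adgre1 returned to 19.8 ± 8.78 CPM (SD, n = 4), Gbp2 to 31.4 ± 12.6 and Col1a1 to 140.0 ± 8.50. Saa3 fell from 2735 ± 519 to 7.20 ± 11.4 CPM (log2 fold change -8.57, SE 1.07, adjusted p = 3.24e-06), and Hmox1 from 140.4 ± 102.9 to 8.18 ± 2.26 CPM. Immediate early and heat shock genes fell in 14 of 15 cases, and 14 adjusted over the list alone (median -1.56, camera adjusted p = 2.57e-09, adjusted p = 0.203 with an estimated correlation). The transcription factor Egr1 was at -3.22. Mesenchymal genes fell in 9 of 14 cases, and 9 adjusted over the list alone (median -1.03, camera adjusted p = 6.27e-06, adjusted p = 0.584 with an estimated correlation).

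Cell-cycle genes fell between 5 and 30 DPA. In the DNA replication list 23 of 28 genes were lower, and 26 adjusted over the list alone (median -1.39, camera adjusted p = 1.06e-10, adjusted p = 0.756 with an estimated correlation). Among these were the thymidine kinase Tk1 (-2.10, SE 0.35, adjusted p = 9.58e-05) and the helicase subunit Mcm7 (-1.20). In the mitosis list 17 of 22 were lower, and 22 adjusted over the list alone (median -1.68, camera adjusted p = 3.24e-08, adjusted p = 0.756 with an estimated correlation). They included survivin (Birc5, -2.25) and the cell-cycle transcription factor Foxm1 (-1.68). Mki67 missed the threshold (-1.46, SE 0.56, adjusted p = 0.0511) and passed without DT 30 DPA replicate 1 (0.0195). Of the cyclins, Ccnd2, the D cyclin of beta cells, rose 1.93-fold (adjusted p = 0.00119) while Ccnd3 fell by 0.95 on the log2 scale (adjusted p = 0.000896). Cdkn1a fell by 1.96 (adjusted p = 0.00204) and the apoptosis gene Bax by 0.71 (adjusted p = 0.000476). With the enterocyte libraries left out, so 1 library at 5 DPA, Mcm7, Birc5, Foxm1, Ccnd2 and Bax were at -1.01, -2.02, -1.31, 0.91 and -0.74 and did not pass (adjusted p = 0.0824, 0.107, 0.208, 0.103 and 0.0593). The p53 targets had 9 of 20 lower and 1 higher, and 11 lower and 1 higher adjusted over the list alone (median -0.45, camera adjusted p = 0.00573, adjusted p = 0.606 with an estimated correlation).

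Endocrine genes rose over the same interval. All 20 secretory granule and exocytosis genes were higher, and 20 adjusted over the list alone (median 1.39, camera adjusted p = 8.53e-10, adjusted p = 0.756 with an estimated correlation). Examples are the vesicle genes Rab3a (2.83-fold), Syt7 (2.66-fold) and Vamp2 (1.99-fold). Their log2 fold changes were 0.82, 0.97 and 0.33 without the libraries with enterocyte RNA, which left 1 library at 5 DPA, and none passed (adjusted p = 0.27, 0.115 and 0.453), nor did Abcc8 (1.003, adjusted p = 0.128) or Gcg (1.15, adjusted p = 0.303). Of 19 beta-cell genes 18 rose, and 19 adjusted over the list alone (median 1.30, camera adjusted p = 1.78e-07, adjusted p = 0.756 with an estimated correlation). They included the zinc transporter Slc30a8 (2.92-fold, adjusted p = 0.00172), the GLP-1 receptor Glp1r (3.77-fold, adjusted p = 0.00169) and the sulfonylurea receptor Abcc8 (2.66-fold). Islet hormone genes rose in 5 of 8 cases, and 6 adjusted over the list alone (median 1.41, camera adjusted p = 0.00448, adjusted p = 0.756 with an estimated correlation). Gcg went from 12493 ± 2437 to 33480 ± 4997 CPM (SD, n = 4 each). Sst rose 4.71-fold (adjusted p = 0.0171, but 0.0572 without DT 5 DPA replicate 4), and Ins2 did not pass (log2 fold change 1.33, SE 0.52, adjusted p = 0.0523) except without DT 5 DPA replicate 3 (0.0385) or DT 30 DPA replicate 2 (0.0465). Sterol and fatty acid synthesis genes rose in 10 of 22 cases, and 10 adjusted over the list alone (median 0.57, camera adjusted p = 0.000654, adjusted p = 0.775 with an estimated correlation), such as the sterol regulator Insig1 (1.79-fold). In the Reg family 3 of 6 genes fell, and 4 adjusted over the list alone (median -4.13, camera adjusted p = 0.0133, adjusted p = 0.756 with an estimated correlation). Reg3b went from 307.0 ± 94.7 to 5.57 ± 4.67 CPM.

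This comparison had the largest number of calls, 5371, of which 2914 were higher and 2457 lower at 30 DPA. Of the 83 genes named by the rule and called, 79 had all 4 libraries on the called side of the mean at 5 DPA. The number fell to 3525 without DT 5 DPA replicate 1 and to 912 without the libraries with enterocyte RNA, which left 1 library at 5 DPA. Of those 912 only 117 were higher (12.8%, against 54.3% of all calls) and 795 lower. The adrenergic genes Dbh and Slc6a2, among the largest rises (log2 fold changes 5.82 and 5.78), were carried by DT 30 DPA replicate 2 and stood at -0.83 and -0.76 without it.

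**Figure D3:**
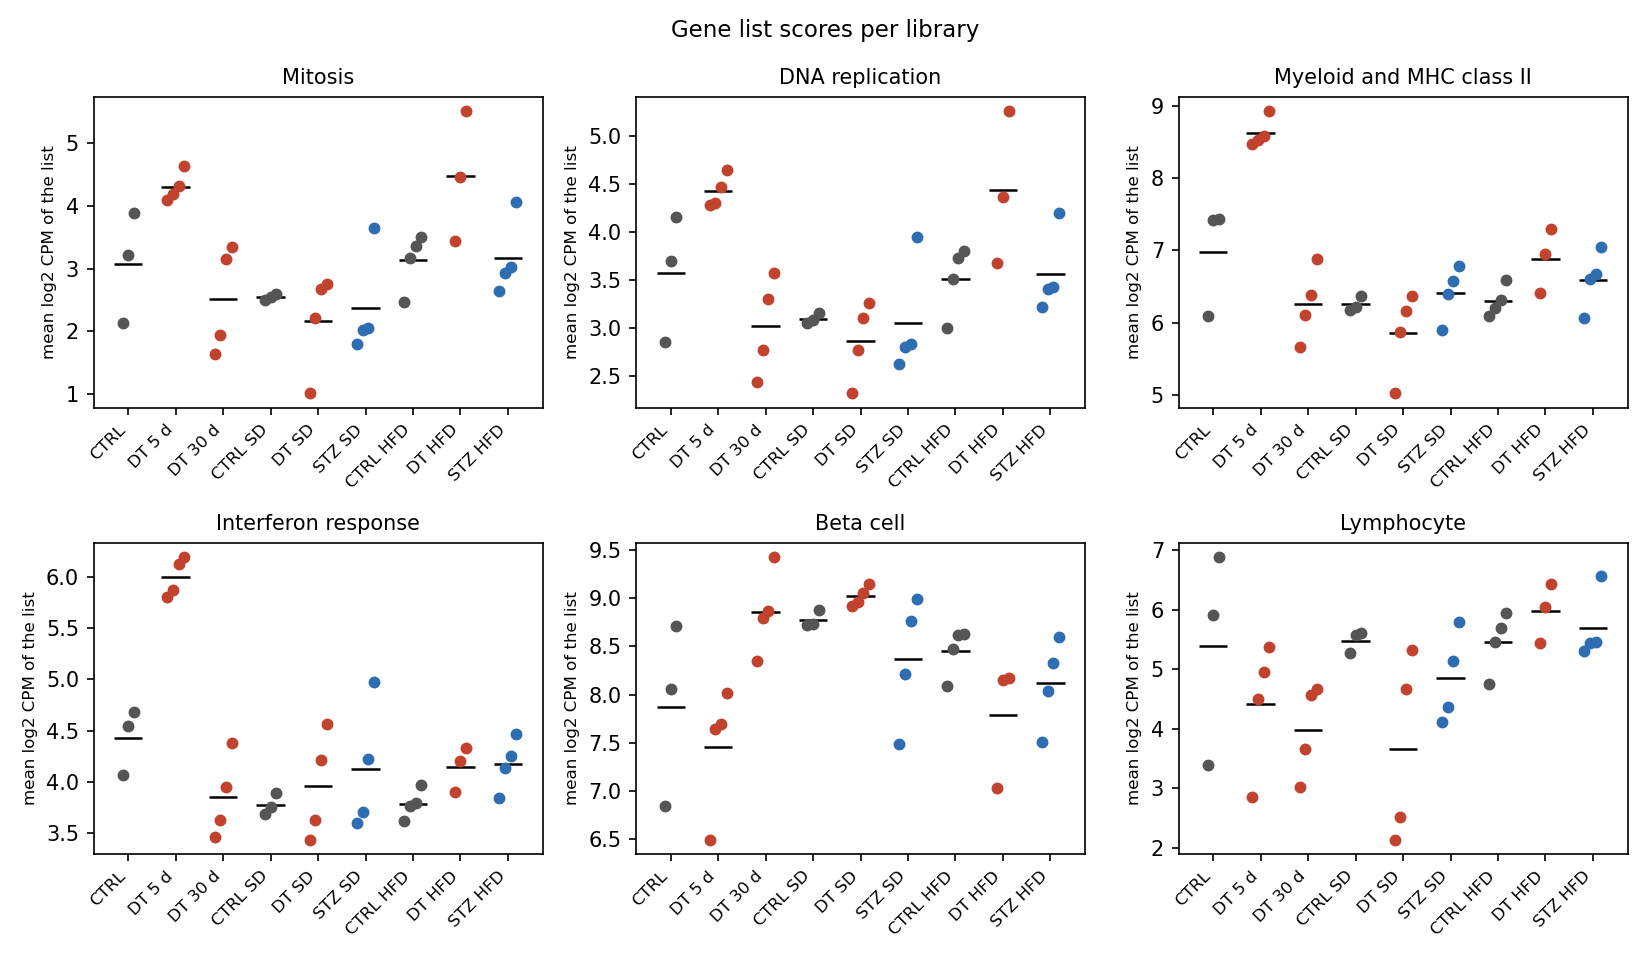
Scores of the mitosis, DNA replication, myeloid and MHC class II, interferon-response, beta-cell and lymphocyte lists (mean log2 CPM of the tested members) per library, 1 point per library and 1 column per group, with a bar at the group mean. The highest mitosis score, 5.52, and a lymphocyte score of 6.42 belong to the same library, DT HFD replicate 2.

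Whether the response at 5 days differed from that at 10 weeks on SD was tested as a difference of effects, each against its own untreated group. The early effect was larger for myeloid genes, with 10 of 20 passing and 13 adjusted over the list alone (median difference 1.86, camera adjusted p = 5.48e-20, adjusted p = 0.56 with an estimated correlation). Adgre1 differed by 3.10 (SE 0.48, adjusted p = 0.0011), and the myeloid lectin Clec4e by 6.19 (SE 1.19, adjusted p = 0.00817). Interferon-response genes differed in 3 of 20 cases, and in 9 adjusted over the list alone (median 1.17, camera adjusted p = 5.26e-11, adjusted p = 0.584 with an estimated correlation). Gbp2 differed by 2.75 (adjusted p = 0.00861). Immediate early and heat shock genes differed in 4 of 15 cases, and in 12 adjusted over the list alone (median 1.32, camera adjusted p = 6.25e-11, adjusted p = 0.203 with an estimated correlation). Mitosis genes (median 1.28, camera adjusted p = 7.74e-08, adjusted p = 0.756 with an estimated correlation) and DNA replication genes (median 0.93, camera adjusted p = 7.87e-08, adjusted p = 0.756 with an estimated correlation) differed as lists, with 0 genes passing over all genes and 0 adjusted over the list alone.

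In all 237 genes had different effects, 212 with the larger log2 fold change at 5 days. The number was 423 without CTRL replicate 2 and 102 without CTRL replicate 3, and 121, 141, 116, 128 and 133 without DT 5 DPA replicate 1, CTRL SD replicates 1, 2 and 3 and DT SD replicate 3. CTRL has no time or diet in its labels, so age and diet may differ between the 2 untreated groups.

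On SD at 10 weeks after DT few genes separated DT from untreated islets. Arntl (BMAL1), the core activator of the circadian clock, fell from 22.4 ± 2.75 CPM (SD, n = 3) to 8.41 ± 1.84 (n = 4), a log2 fold change of -1.41 (SE 0.20, adjusted p = 0.00152). Erdr1, which the annotation places on the Y chromosome (90784738 to 90816464), fell from 194.8 ± 20.7 to 52.6 ± 14.2 CPM (adjusted p = 0.00152). The immunoglobulin segment Ighj1 (log2 fold change -3.71, adjusted p = 0.0231) and Nab2, a repressor of early growth response factors (-1.06, adjusted p = 0.013), also fell. The transcription factor Hbp1 rose 1.49-fold (adjusted p = 0.0155). Gm21887, outside the rule and named after its values were seen, was the remaining call (-2.99, SE 0.49, adjusted p = 0.00865).

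None of the fixed genes passed edgeR's test on SD, although the libraries of the 2 groups lay apart in some. Ins1 was at 64120 to 74649 CPM after DT and 44613 to 50197 in CTRL (log2 fold change 0.53, SE 0.52, adjusted p = 0.826), and Ins2 at 152040 to 165310 and 108320 to 123310. Mafa was at 56.6 to 91.2 and 103.7 to 134.7 CPM (-0.73, SE 0.43, adjusted p = 0.68), while Mki67 was at -0.08 (SE 0.60, adjusted p = 0.991). Lymphocyte genes were lower after DT as a list (median -1.27, 0 of 15 over all genes and 0 adjusted over the list alone, camera adjusted p = 8.81e-10, adjusted p = 0.743 with an estimated correlation). Their score was 2.513, 4.671, 2.133 and 5.325 in DT SD replicates 1 to 4 against 5.265 to 5.604 in CTRL SD. Erythroid (median 1.65 over 5 genes) and unfolded protein response genes (0.23 over 24) were higher as lists. Of each 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000956 and 0.000353, adjusted p = 0.743 and 0.756 with an estimated correlation). In all 6 genes were called by edgeR and 154 by DESeq2, and edgeR called 22 without the libraries with enterocyte RNA. The number was 2 without CTRL SD replicate 3, DT SD replicate 1 or DT SD replicate 3. The calls of Hbp1 and Nab2 also ended without CTRL SD replicate 2 (adjusted p = 0.304 and 0.192), that of Hbp1 without DT SD replicate 4 (0.0664) and that of Ighj1 without DT SD replicates 2 and 4 (0.109 and 0.0664).

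STZ on SD was marked by genes of fatty acid oxidation and the respiratory chain in a subset of libraries. All 15 fatty acid oxidation genes were above CTRL SD (median log2 fold change 0.97), 0 passing over all genes and 15 adjusted over the list alone (camera adjusted p = 1.19e-11, adjusted p = 0.584 with an estimated correlation). Oxidative phosphorylation genes were higher as a list (median 0.49, 0 of 21 over all genes, 11 adjusted over the list alone, camera adjusted p = 1.69e-10, adjusted p = 0.743 with an estimated correlation). So were oxidative stress and metallothionein genes (median 0.75, 0 of 13 over all genes, 9 adjusted over the list alone, camera adjusted p = 6.54e-06, adjusted p = 0.584 with an estimated correlation). STZ SD replicates 1 and 4 held the most enterocyte RNA of all libraries, and without the libraries with such RNA the 3 medians were 0.05, 0.09 and 0.08. Insulin, glucagon and proliferation genes did not separate STZ from CTRL on SD (Ins2 -0.21, SE 0.55, adjusted p = 0.978, and Mki67 0.12, SE 0.60, adjusted p = 0.989).

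The single gene called between STZ and CTRL on SD was Rps2, a protein of the small ribosomal subunit (chromosome 17, 24718116 to 24721929), at 257.0 ± 118.5 CPM (SD, n = 4) against 72.3 ± 3.14 (n = 3), with a log2 fold change of 1.83 (SE 0.30, adjusted p = 0.0377). By edgeR 0 genes were called without CTRL SD replicate 1, 2 or 3 (Rps2 adjusted p = 0.269, 0.158 and 0.309), and 9, 486, 467 and 4 without STZ SD replicates 1, 2, 3 and 4. The DESeq2 Wald test called 689 genes, edgeR 15 without the libraries with enterocyte RNA, and 5 with hormone genes left out before scaling, of which 3 were higher and 2 lower.

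On HFD at 10 weeks the DT islets had higher cell-cycle lists than CTRL HFD islets, with the highest mitosis score, 5.52, in DT HFD replicate 2. Mitosis genes had a median log2 fold change of 1.54, with 0 of 22 passing over all genes and 21 adjusted over the list alone (camera adjusted p = 7.51e-12, adjusted p = 0.743 with an estimated correlation). DNA replication genes had one of 0.98, with 0 of 28 and 22 (adjusted over the list alone; camera adjusted p = 2.37e-12, adjusted p = 0.743 with an estimated correlation). Mki67 stood at 211.3 ± 155.9 CPM (SD, n = 3) in DT HFD and 52.7 ± 18.6 (n = 4) in CTRL HFD and did not pass (log2 fold change 2.00, SE 0.60, adjusted p = 0.33). The same library had a lymphocyte score of 6.42 and a germinal centre B cell score of 7.10. Secretory granule genes (median -0.55), beta-cell genes (-0.55) and acinar genes (-1.70) were lower as lists, with 0 passing over all genes and 0 adjusted over the list alone in each (camera adjusted p = 3.61e-07, 6.42e-06 and 4.73e-06; adjusted p = 0.756, 0.775 and 0.798 with an estimated correlation).

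Rps2 was again the single gene called between DT and CTRL on HFD, at 269.4 ± 45.6 CPM (SD, n = 3) against 68.3 ± 12.6 (n = 4), with a log2 fold change of 1.98 (SE 0.29, adjusted p = 0.00421). The call ended without CTRL HFD replicate 5 (adjusted p = 0.055) and without DT HFD replicate 2 (0.0667), which left 0 called genes, and 17 were called without DT HFD replicate 1. Without the libraries with enterocyte RNA, the same replicate 1, edgeR called 822 genes in a smaller fit, and DESeq2 called 63 of all libraries.

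After STZ on HFD Rps2 rose from 68.3 ± 12.6 CPM (SD, n = 4) to 403.0 ± 135.9 (n = 4), a log2 fold change of 2.56 (SE 0.28, adjusted p = 1.91e-05). Other rises were the antiproliferative gene Btg3 (6.30-fold), the zinc finger gene Zfp97 (4.18-fold), the inhibitory receptor of myeloid cells Pirb (3.73-fold) and the smooth muscle gene Ppp1r14a (3.38-fold). The zinc finger gene Zfp605 fell (log2 fold change -1.33, SE 0.20, adjusted p = 0.00207), as did Arntl (-0.92, SE 0.19, adjusted p = 0.0352), the anion exchanger Slc26a1 (-2.37) and the lactate receptor Hcar1 (-1.46). Alpha-cell genes were lower as a list (median -0.80, 0 of 11 over all genes, 3 adjusted over the list alone, camera adjusted p = 5.99e-06, adjusted p = 0.743 with an estimated correlation). Oxidative phosphorylation genes were higher (median 0.33, 0 of 21 and 5 adjusted over the list alone, camera adjusted p = 0.000337, adjusted p = 0.798 with an estimated correlation) and mesenchymal genes higher (median 0.41, 1 of 14 and 3 adjusted over the list alone, camera adjusted p = 0.000443, adjusted p = 0.743 with an estimated correlation).

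In total 83 genes were called between STZ and CTRL on HFD, 58 higher and 25 lower, and the 13 genes named by the rule had all 4 STZ libraries on the called side of the CTRL mean. The number was 196, 9, 221 and 8 without STZ HFD replicates 1, 2, 3 and 4, and 12, 6 and 14 without CTRL HFD replicates 3, 4 and 5. Rps2 and Zfp605 stayed called in each of these fits, while Btg3, Zfp97, Arntl, Slc26a1, Hcar1, Pirb and Ppp1r14a each lost the call in at least 4 of them.

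Diet alone, HFD against SD in untreated mice, gave 0 genes by edgeR at an adjusted p below 0.05, 439 at an unadjusted p below 0.05, and 24 by DESeq2. Mitosis genes (median log2 fold change 0.73, all 22 above 0, camera adjusted p = 2.82e-06, adjusted p = 0.775 with an estimated correlation) and DNA replication genes (0.45, 27 of 28 above 0, camera adjusted p = 3.37e-06, adjusted p = 0.775 with an estimated correlation) were higher on HFD as lists, with 0 genes passing over all genes and 0 adjusted over the list alone. Mki67 was 26.6 ± 1.68 CPM (SD, n = 3) on SD and 52.7 ± 18.6 (n = 4) on HFD (log2 fold change 0.98, SE 0.61, adjusted p of 1 by edgeR). Ins1 was at -0.93 (SE 0.51) with the same adjusted p.

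After DT, islets of mice on HFD had more cell-cycle and immune transcripts and fewer endocrine ones than those on SD. Mki67 went from 25.2 ± 14.5 CPM (SD, n = 4) to 211.3 ± 155.9 (n = 3), a log2 fold change of 3.07 (SE 0.62, adjusted p = 0.00459), and Top2a from 22.3 ± 11.1 to 136.0 ± 97.4 CPM (2.60, SE 0.60, adjusted p = 0.0058). All 22 mitosis genes rose, and 22 adjusted over the list alone (median 2.40, camera adjusted p = 5.3e-12, adjusted p = 0.743 with an estimated correlation). Instances are the kinetochore motor Cenpe (6.66-fold) and the checkpoint kinase Bub1b (5.83-fold). Of 28 DNA replication genes 25 rose, and 27 adjusted over the list alone (median 1.57, camera adjusted p = 5.59e-12, adjusted p = 0.743 with an estimated correlation). The sliding clamp Pcna was 2.42-fold and Mcm7 2.67-fold higher.

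Lymphocyte genes rose in 7 of 15 cases on HFD after DT, and in 11 adjusted over the list alone (median 1.85, camera adjusted p = 8.91e-06, adjusted p = 0.775 with an estimated correlation). Myeloid genes rose in 10 of 20, with 13 higher and 1 lower adjusted over the list alone (median 1.05, camera adjusted p = 7.58e-05, adjusted p = 0.775 with an estimated correlation). Among these were the dendritic cell integrin Itgax (4.13-fold) and the MHC class II gene H2-Ab1 (3.18-fold). Beta-cell genes fell in 11 of 19 cases, and in 13 adjusted over the list alone (median -1.20, camera adjusted p = 6.78e-07, adjusted p = 0.756 with an estimated correlation). The glucose-6-phosphatase of islets G6pc2 was at -2.04 (SE 0.48, adjusted p = 0.00623) and the prohormone convertase Pcsk1 at -1.55. Secretory granule genes fell in 12 of 20 cases, and in 18 adjusted over the list alone (median -0.97, camera adjusted p = 2.69e-07, adjusted p = 0.756 with an estimated correlation), such as secretogranin Scg2 (-1.59). Endothelial genes fell in 7 of 15 cases, and in 11 adjusted over the list alone (median -0.66, camera adjusted p = 6.07e-05, adjusted p = 0.756 with an estimated correlation), including the angiopoietin receptor Tek (-1.25). Acinar genes were lower as a list (median -2.87, 2 of 25 over all genes and 0 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.798 with an estimated correlation). Of 24 genes of the unfolded protein response 6 fell, and 9 adjusted over the list alone (median -0.39, camera adjusted p = 0.00124, adjusted p = 0.775 with an estimated correlation; 0.0985 with the preset correlation without DT HFD replicate 1 and 0.162 without the libraries with enterocyte RNA).

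The diet comparison after DT called 4136 genes, 2646 higher and 1490 lower on HFD, and it rested on 1 library. Without DT HFD replicate 2 edgeR called 0 genes (Mki67 2.33, adjusted p = 0.095), without DT HFD replicate 3 2629, and without DT SD replicates 1 and 3 2244 and 1967. DT HFD replicate 2 carried the high lymphocyte and germinal centre scores given above, and with lymphocyte and enterocyte scores as covariates edgeR again called 0 genes. Among the 68 genes named by the rule and called, 66 had all 3 HFD libraries on the called side of the SD mean.

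In the diet comparison after STZ, STZ SD replicates 1 and 4 held 11290 and 17671 CPM of enterocyte markers. Gsta2, a glutathione transferase, was at 25.02 ± 34.0 CPM (SD, n = 4) on SD and 0.127 ± 0.150 (n = 4) on HFD (log2 fold change -7.44, SE 1.44, adjusted p = 0.044). The aldo-keto reductase Akr1b8 (-4.89), the gluconeogenic enzyme Fbp1 (-4.84) and the quinone reductase Nqo1 (-3.44) fell too. Fatty acid oxidation genes were lower as a list (median -1.29, 0 of 15 over all genes, 15 adjusted over the list alone, camera adjusted p = 2.89e-12, adjusted p = 0.584 with an estimated correlation). So were oxidative stress and metallothionein genes (median -0.84, 2 of 13 over all genes, 10 adjusted over the list alone, camera adjusted p = 4.86e-08, adjusted p = 0.56 with an estimated correlation). Mitosis genes were higher as a list (median 0.75, 0 of 22 over all genes and 0 adjusted over the list alone, camera adjusted p = 3.99e-06, adjusted p = 0.775 with an estimated correlation), and their median was -0.11 with lymphocyte and enterocyte scores as covariates.

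The 24 genes called by diet after STZ were all lower on HFD, and without the libraries with enterocyte RNA edgeR called 0 and the fatty acid oxidation median was -0.05. The number was 1, 0, 1 and 0 without STZ HFD replicates 1, 2, 3 and 4, and 0, 521, 941 and 0 without STZ SD replicates 1, 2, 3 and 4, and DESeq2 called 611.

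Whether diet changed the effect of ablation was tested as an interaction. For DT by diet edgeR called 0 genes (2751 at an unadjusted p below 0.05, and 106 by DESeq2), and Mki67 had an interaction of 2.08 (SE 0.84, adjusted p = 0.282). Mitosis genes (median 1.83), DNA replication genes (1.17) and lymphocyte genes (1.69) passed as lists, with 0 genes passing over all genes and 0 adjusted over the list alone (camera adjusted p = 2.19e-08, 3.86e-08 and 2.9e-06; adjusted p = 0.756 for each with an estimated correlation). For STZ by diet edgeR called 0 genes (1163 at an unadjusted p below 0.05, and 54 by DESeq2). Fatty acid oxidation genes had a median interaction of -1.33, with 0 of 15 passing over all genes and 12 lower adjusted over the list alone (camera adjusted p = 1.2e-11, adjusted p = 0.584 with an estimated correlation), and of -0.06 without the libraries with enterocyte RNA.

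The ablation methods were compared directly at 10 weeks. On SD, fatty acid oxidation and early response genes were higher as lists after STZ than after DT. Of 15 fatty acid oxidation genes 8 were higher, and 13 adjusted over the list alone (median 0.90, camera adjusted p = 7.75e-08, adjusted p = 0.743 with an estimated correlation). They included the carnitine carrier Slc25a20 (3.04-fold) and the thiolase Acaa2 (2.86-fold). Without the libraries with enterocyte RNA the median was -0.05. Vip, a neuropeptide, stood at 12.3 ± 6.49 CPM (SD, n = 4) after STZ and 135.6 ± 55.8 (n = 4) after DT (log2 fold change -3.47, SE 0.57, adjusted p = 0.00839), and the neuropeptide genes Grp (-3.30) and Tac1 (-2.62) were lower too. The early response genes Fos (3.64-fold) and Junb (2.40-fold) were higher, within a list of 15 in which 4 passed, and 4 adjusted over the list alone (median 0.51, camera adjusted p = 0.000296, adjusted p = 0.645 with an estimated correlation). Cdkn1a was 3.64-fold higher (adjusted p = 0.0324) at 34.7 ± 28.1 against 9.55 ± 2.11 CPM, and the p53 target Pmaip1 3.85-fold (adjusted p = 0.0369). Cdkn1a stood at 45.4 and 69.6 CPM in STZ SD replicates 1 and 4, which held the most enterocyte RNA, and at 11.7 and 12.04 in the other 2. The log2 fold changes of Cdkn1a and Pmaip1 were 0.31 and 0.56 without the libraries with such RNA (adjusted p = 0.711 and 0.684).

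Beta-cell genes were lower after STZ than after DT on SD as a list (median -0.50, 0 of 19 over all genes and 0 adjusted over the list alone, camera adjusted p = 2.28e-05, adjusted p = 0.775 with an estimated correlation; -0.07 with lymphocyte and enterocyte scores as covariates). So were genes of the unfolded protein response (median -0.34, 2 of 24 lower, 7 adjusted over the list alone, camera adjusted p = 9.93e-05, adjusted p = 0.756 with an estimated correlation), namely Pdia6 (-0.70) and Calr (-0.58). The comparison called 451 genes, 380 higher and 71 lower, and 3 without the libraries with enterocyte RNA. Of the 33 genes named by the rule and called, 26 had all 4 STZ libraries on the called side of the DT mean, and the fewest was 2. The number was 9, 1254, 1050 and 60 without STZ SD replicates 1, 2, 3 and 4 and 4, 20, 4 and 86 without DT SD replicates 1, 2, 3 and 4. Of the genes named here Vip alone kept its call without each of these 8 libraries, and it lost it without the libraries with enterocyte RNA (-3.15, adjusted p = 0.118).

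On HFD, mesenchymal and endothelial genes were higher after STZ than after DT as lists, and mitosis and DNA replication genes lower. Mustn1, a gene of the musculoskeletal system, was 3.87-fold higher (adjusted p = 0.00517), the calcification inhibitor Mgp 4.04-fold, and the contractile genes Tpm2, Tagln and Myl9 3.10-, 3.11- and 2.85-fold. Mesenchymal genes (median 0.66) were higher in 1 of 14 cases and endothelial ones (0.46) in 1 of 15, the vessel gene Egfl7. Adjusted over the list alone 3 and 4 were higher (camera adjusted p = 4.47e-06 and 9.34e-06, adjusted p = 0.584 and 0.756 with an estimated correlation). Mybl1, a transcription factor of germinal centre and germ cells, was at 6.05 ± 2.61 CPM (SD, n = 4) after STZ and 42.4 ± 37.5 (n = 3) after DT (log2 fold change -2.80, SE 0.60, adjusted p = 0.0418), and Arntl was lower (-1.07, SE 0.20, adjusted p = 0.0403). Mitosis (median -1.41, 0 of 22 over all genes, 17 adjusted over the list alone) and DNA replication genes (-0.98, 0 of 28 and 15) were lower as lists (camera adjusted p = 6.25e-11 and 1.69e-10, adjusted p = 0.756 for each with an estimated correlation). The germinal centre B cell score was 5.83 to 7.10 in DT HFD, highest in replicate 2 as was the mitosis score, against 4.67 to 5.60 in STZ HFD. Acinar genes were higher as a list (median 3.58, 0 of 25 over all genes, 24 adjusted over the list alone, camera adjusted p = 6.54e-06, adjusted p = 0.806 with an estimated correlation; 0.0908 with the preset correlation without STZ HFD replicate 4).

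Between STZ and DT on HFD 60 genes were called, 15 higher and 45 lower. The number was 125, 100, 2 and 1 without STZ HFD replicates 1, 2, 3 and 4 and 290, 1 and 2 without DT HFD replicates 1, 2 and 3, and 605 without the libraries with enterocyte RNA. Mustn1 lost its call without DT HFD replicate 3 (adjusted p = 0.0682), and the other genes named here lost theirs without STZ HFD replicates 3 and 4 and DT HFD replicates 2 and 3.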

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

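All tests of explanations and of other splits of the libraries in this part were chosen after the results were seen, while the tests between groups were planned.

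Mitosis genes were higher at 5 days after DT than in CTRL (median log2 fold change 1.13, quartiles 0.93 and 1.204, median SE 0.59, 0 of 22 called by edgeR) and higher on HFD than on SD after DT (2.40, quartiles 2.25 and 2.52, median SE 0.58, 22 of 22 called). RNA of lymphocytes or enterocytes is argued against at 5 days: with both marker scores as covariates the median was 1.99 (quartiles 1.75 and 2.24, median SE 0.41, 22 of 22 called), and the lymphocyte list was lower at 5 days (-1.37). On HFD such RNA may account for part of the rise, since with the same covariates the median was 1.05 (quartiles 0.96 and 1.197, median SE 0.46, 0 called, because the fold change was smaller) and the lymphocyte list was higher (1.85). Dividing myeloid cells stay open at 5 days, where the myeloid list had a median of 1.67, since bulk RNA does not show which cells divide. Dividing beta cells remain an untested possibility for both, where the design names ablation as the difference at 5 days and diet after DT.

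H2-Ea-ps, a pseudogene of the MHC region (chromosome 17, 34341959 to 34344645), ranged from 1.28 to 164.3 CPM in the 10 untreated libraries and stood at or below 0.238 CPM in the DT libraries other than those at 30 DPA, which held 12.8 to 58.8 CPM. The toxin as the cause in every group that received it is argued against, since 4 of 15 DT libraries, all at 30 DPA, reached the lowest untreated library. A strain variant of the region is a candidate explanation: 14 of the 50 genes that varied most with H2-Ea-ps within groups lay within 10 Mb of it, against a 99th percentile of 5 over 1000 random genes, of which 2 had as many. Of 11 further genes tested in the same way, Msh5 in the same region gave 7 and the others at most 2; for Hist1h2bk, Ifi44l and Ifi202b, higher in most DT libraries than in untreated ones, the most was 2, which leaves a variant open. Called genes lay close together more often than in 95% of random sets in 1 of 7 comparisons (STZ against DT on SD, 256 genes against 233), so whether strain segments contribute to the calls stays open.

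Hbegf was low relative to Ins2 in the DT libraries, with a median log2 ratio of -13.24 and 15 of 15 below the lowest untreated library (-10.40). Loss of the cells that carry the toxin receptor is consistent with this if reads of the transgene were counted under Hbegf, which was not tested. Less beta-cell RNA in the libraries is argued against, since 15 of 15 DT libraries also lay below every untreated library in Hbegf relative to the beta-cell score. In STZ libraries the median was -12.98 and 6 of 8 lay below, while STZ SD replicate 1 was at -10.27 and STZ HFD replicate 1 at -7.76, so STZ mice without the transgene remain open, although the labels give every mouse the same genotype. The position test does not exclude a strain variant near Hbegf (0 of 50 genes within 10 Mb).

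Within groups of 4 libraries 120 values were examined and 12 lay far from the others of their group, where about 1 in 20, or 6, would by chance. These were 40900 CPM of Gcg in DT 30 DPA replicate 3, 1208 CPM of Ppy in DT 5 DPA replicate 1 and 7798 in DT SD replicate 3, and 28.2 CPM of Mafa in STZ HFD replicate 2. STZ SD replicate 1 stood apart in Mki67 (64.9 CPM), Top2a (56.4 CPM), the mitosis score (3.65) and the DNA replication score (3.95). The others were the lymphocyte score of STZ HFD replicate 2 (6.57), the acinar share of DT 5 DPA replicate 3 (8.83%), and the enterocyte sums of DT 30 DPA replicate 2 (3613 CPM) and STZ HFD replicate 1 (165.7 CPM).

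Groups under the same treatment differed between times. Between 30 and 5 days after DT 5371 genes differed by edgeR, 3525 without DT 5 DPA replicate 1. With the preset correlation 12 lists differed, while with an estimated one 0 of all list tests passed, which holds for each list in this part. Lower at 30 days were the myeloid (-2.41), interferon-response (-2.14), mitosis (-1.68), immediate early (-1.56), DNA replication (-1.39), mesenchymal (-1.03), p53 target (-0.45) and Reg (-4.13) lists. Higher were the hormone (1.41), secretory granule (1.39), beta-cell (1.30) and sterol (0.57) lists. Genes of the endocrine cell were higher, with log2 fold changes of 1.30 for Ins1, 1.42 for Gcg, 2.23 for Sst, 1.204 for Mafa, 1.26 for Slc2a2, 1.54 for Slc30a8, 1.41 for Abcc8, 1.91 for Glp1r, 1.41 for Syt7, 0.99 for Vamp2 and 1.502 for Rab3a. So were Ccnd2 (0.95), Lss (0.83) and Insig1 (0.84), and, through DT 30 DPA replicate 2, Dbh (5.82) and Slc6a2 (5.78), which were at -0.83 and -0.76 without it. Cell-cycle and p53 genes were lower, with -1.65 for Top2a, -1.96 for Cdkn1a, -2.10 for Tk1, -1.41 for Tyms, -1.20 for Mcm7, -2.25 for Birc5, -1.89 for Prc1, -1.68 for Foxm1, -0.71 for Bax and -0.95 for Ccnd3. Inflammatory and stress genes were lower too, with -3.52 for Adgre1, -2.98 for Fcer1g, -3.47 for Gbp2, -2.79 for Gbp3, -2.17 for Col1a1, -5.78 for Reg3b, -5.28 for Reg3g, -8.56 for Saa3, -7.49 for Serpinb2, -3.22 for Egr1 and -4.10 for Hmox1. The calls of Ins1, Sst, Mafa, Slc2a2 and Top2a ended without 1 library: Ins1 without DT 5 DPA replicates 1, 2 and 4 (adjusted p = 0.143, 0.0815 and 0.0693) and DT 30 DPA replicates 1, 3 and 4 (0.0784, 0.0558 and 0.128), Sst without DT 5 DPA replicate 4 (0.0572), Mafa and Slc2a2 without DT 5 DPA replicate 1 (0.104 and 0.0806) or DT 30 DPA replicate 4 (0.107 and 0.115), and Top2a without DT 5 DPA replicate 1 (0.0668) or DT 30 DPA replicates 2 and 4 (0.083 and 0.0829).

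The effect of DT at 5 days differed from that at 10 weeks in 237 genes and in the myeloid (1.86), immediate early (1.32), mitosis (1.28), interferon-response (1.17) and DNA replication (0.93) lists. The named genes were Acod1 (8.34), Serpinb2 (6.58), Clec4d (6.48), Clec4e (6.19), Cxcl10 (3.65), Itgam_1 (3.49), Adgre1 (3.10), Fosb (2.99), Gbp2 (2.75), Hspa1a (2.22), Col3a1 (1.72) and the clock gene Per3 (-2.60). Without 1 library the number was 423 (CTRL replicate 2), 102 (CTRL replicate 3), 121 (DT 5 DPA replicate 1), 141, 116 and 128 (CTRL SD replicates 1, 2 and 3) and 133 (DT SD replicate 3). The calls of Acod1, Clec4d and Serpinb2 ended without CTRL SD replicate 1 (adjusted p = 0.0746, 0.163 and 0.228), of Cxcl10 without CTRL replicate 3 (0.0678), of Fosb without CTRL SD replicate 2 (0.0614) and of Col3a1 without CTRL SD replicates 1 and 2 and DT SD replicate 3 (0.0847, 0.0541 and 0.0517). That of Hspa1a ended without CTRL replicates 1 and 3 (0.101 and 0.0624), DT 5 DPA replicates 1 and 3 (0.0791 and 0.0714), CTRL SD replicates 1, 2 and 3 (0.0512, 0.126 and 0.0553) and DT SD replicates 1, 2 and 4 (0.0619, 0.0742 and 0.0649). That of Per3 ended without CTRL replicate 3 (0.245), DT 5 DPA replicates 1, 2 and 4 (0.0549, 0.0533 and 0.0546), CTRL SD replicates 1, 2 and 3 (0.0615, 0.0867 and 0.0769) and DT SD replicates 2 and 3 (0.0551 and 0.0516). With the preset correlation the effect of DT differed between diets for the mitosis (1.83), lymphocyte (1.69) and DNA replication (1.17) lists. That of STZ differed for the fatty acid oxidation list (-1.33), whose median was -0.06 without the libraries with enterocyte RNA. In the joint fit edgeR called 0 genes in either interaction.

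The library in no group, titled as untreated on HFD and labelled as treated with DT, lay above every untreated library in 8 of 18 genes compared. These were Rps2 (324.4 CPM), Hbegf (256.4), Top2a (106.1), Mki67 (102.9), Ifi202b (19.96), Zfp97 (11.03), Hist1h2bk (3.35) and Ifi44l (0.248). No explanation was tested for this library.

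Other splits of the same libraries, fitted alone, were set beside the real split to ask whether chance could give as many calls. Only the real split called as many genes for DT 5 DPA against CTRL (320 genes, 29 in the highest other split) and DT 30 DPA against DT 5 DPA (5133 and 304). The same was seen for DT against CTRL on SD (27 and 1) and HFD against SD after DT (3371 and 0). A share of 1 of 35 splits is the smallest possible, with no allowance for reading 15 comparisons. It argues against chance in these comparisons without excluding it. Without DT HFD replicate 2 the joint fit called 0 genes for HFD against SD after DT. The fits of the compared libraries alone called 297 of the 949, 4376 of the 5371, 2 of the 6 and 2702 of the 4136 genes of the joint fit, and the others are not tested. For DT (3 and 2) and STZ (2 and 0) against CTRL on HFD the share was also 1 of 35, but such small differences leave chance open, and in the latter only 1 of the 83 genes of the joint fit was called. Chance cannot be excluded for HFD against SD in CTRL either. There 5 of 35 splits called at least the real 1 gene and the highest other 47, which points to a structure of these libraries that was not identified. Nor can chance be excluded for STZ against DT on HFD (1 gene, 12 in the highest other, 2 of 35), which points to such a structure too. The same holds for the DT by diet interaction (2 and 2, 2 of 40) and the difference between 5 days and 10 weeks (144 and 157, 2 of 40). In the fits of the compared libraries alone 0 genes were called for DT 30 DPA against CTRL (highest other 1), STZ against CTRL on SD (3), HFD against SD after STZ (0) and STZ against DT on SD (0), so all 35 splits called as many, and all 40 did for STZ by diet (0).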

How the results depend on the processing

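The fits with lymphocyte and enterocyte scores and those without the libraries with enterocyte RNA were tests chosen after the results were seen, as were other settings for list medians except the block, the correlations and leaving out 1 library. The rest were planned, and counts are by edgeR unless DESeq2 is named. Of the 163 named gene calls 163 held with DESeq2 size factors, 126 without the low-count filter, 124 with the replicate block, 123 with the acinar score, 103 with both scores, 91 without the libraries with enterocyte RNA, and of 161 all 161 with DESeq2 and 88 with the compared groups alone. Of 78 list calls 0 held with an estimated correlation, 32 with fry and 68 without those libraries. Of 435 list tests 163 passed, 0 with an estimated correlation and 35 with fry. Where a count moved by more than 1.5 times the cause was not tested, except that leaving out libraries and fitting fewer groups leaves fewer samples. DT 5 DPA against CTRL called 2883 genes with both scores, 329 without the libraries with enterocyte RNA and 320 with the compared groups alone. DT 30 DPA against CTRL called 72 with DESeq2 size factors, 1 with no filter, 259 with a stricter one, 312 without hormone genes, 4 with the acinar score, 6 with both scores, 1849 with DESeq2, and 0 without the libraries with enterocyte RNA, with the compared groups alone or with the block. DT 30 DPA against DT 5 DPA called 912 without the libraries with enterocyte RNA. On SD, DT against CTRL called 22 without those libraries, 154 with DESeq2 and 27 with the compared groups alone. STZ against CTRL on SD called 5 without hormone genes, 3 with the acinar score, 4 with both scores, 15 without the libraries with enterocyte RNA, 689 with DESeq2, and 0 with the compared groups alone or the block. On HFD, DT against CTRL called 822 without the libraries with enterocyte RNA, 63 with DESeq2 and 3 with the compared groups alone. STZ against CTRL on HFD called 20 with no filter, 125 with the acinar score, 6 with the block, 357 with both scores, 229 without the libraries with enterocyte RNA, 481 with DESeq2 and 2 with the compared groups alone. HFD against SD called 24 with DESeq2 and 1 with the compared groups alone in CTRL. After DT it called 928 with the acinar score, 0 with both scores and 6481 without the libraries with enterocyte RNA. After STZ it called 14 without hormone genes, 121 with the acinar score, 611 with DESeq2, and 0 with no filter, the block, both scores, the compared groups alone or without the libraries with enterocyte RNA. DT by diet called 349 without those libraries, 106 with DESeq2 and 2 with the compared groups alone, and STZ by diet 54 with DESeq2. STZ against DT on SD called 119 with no filter, 31 with the acinar score, 225 with the block, 8 with both scores, 3 without the libraries with enterocyte RNA, 1340 with DESeq2 and 0 with the compared groups alone. On HFD it called 5 with no filter, 1 with the acinar score, 8 with the block, 417 with both scores, 605 without the libraries with enterocyte RNA, 663 with DESeq2 and 1 with the compared groups alone. The difference between 5 days and 10 weeks had 594 genes with both scores, 112 without the libraries with enterocyte RNA, 588 with DESeq2 and 144 with the compared groups alone. Replicate numbers do not pair the libraries: correlations of same-numbered libraries ran from -0.178 to 0.647, and every library correlated best with its own number only for STZ against CTRL on SD (6 of 6). The block moved no other count by more than 1.5 times. Leaving out 1 library gave 586 to 1269 genes for DT 5 DPA against CTRL, 0 to 4273 for DT 30 DPA against CTRL and 3525 to 5442 for DT 30 DPA against DT 5 DPA. It gave 2 to 6 (DT) and 0 to 486 (STZ) against CTRL on SD, 0 to 17 (DT) and 6 to 221 (STZ) against CTRL on HFD, 0 to 4998 for diet after DT, 0 to 941 for diet after STZ, 4 to 1254 and 1 to 290 for STZ against DT on SD and HFD, 102 to 423 for 5 days against 10 weeks, and 0 throughout for diet in CTRL and both interactions. Some values reversed. With both scores the lymphocyte medians, which that fit removes by construction, were 0.022 (DT 5 DPA) and 0.045 (DT 30 DPA) against CTRL, 0.055 (DT on SD) and -0.065 (diet after DT), and the mitosis median for diet after STZ was -0.11. With the acinar score the acinar medians, removed likewise, were -0.009 (DT 5 DPA) and 0.11 (diet after DT). Without the libraries with enterocyte RNA the fatty acid oxidation median was -0.05 for STZ against DT on SD, with Cat at -0.11 and Nqo1 at -0.53, Akr1b8 was 0.19 for diet after STZ, and Dbh and Slc6a2 were -2.35 and -2.31 between 30 and 5 days (from -0.83 to 7.14 and from -0.76 to 7.205 when leaving out 1 library, lowest without DT 30 DPA replicate 2). Another scaling moved the median of all genes by -0.05 to 0.03.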

Other observations

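The tests of circadian clock genes, single genes and correlations in this part were chosen after the results were seen, and no list of clock genes was tested. Arntl, the activator of the clock, ran from 19.3 to 24.7 CPM in CTRL SD and from 5.89 to 10.3 in DT SD, and from 7.36 to 15.7 over the 8 STZ libraries. In CTRL HFD and DT HFD it ran from 15.2 to 17.7 and from 15.6 to 20.4, and in CTRL, DT 5 DPA and DT 30 DPA from 18.3 to 26.5, 20.9 to 29.7 and 21.4 to 26.6. Dbp and Per3, targets of the clock, did not pass on SD: Dbp ran from 19.9 to 39.3 CPM in CTRL SD and from 80.2 to 106.4 in DT SD (log2 fold change 1.51, SE 0.40, edgeR adjusted p = 0.239), and Per3 from 11.4 to 13.5 and from 21.7 to 34.6 (1.25, SE 0.44, adjusted p = 0.478). Ciart, a repressor of the clock, was called higher at 5 DPA than in CTRL (log2 fold change 3.71, SE 0.55, adjusted p = 7.87e-05), at 15.9 to 56.6 CPM in the 4 libraries against 1.80 to 2.26 in CTRL, and no fit leaving out 1 library was made for it. The hour of collection is not given in the sources used here.

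Rps2 ran from 54.7 to 115.2 CPM in the 10 untreated libraries, from 143.2 to 318.9 in the 15 DT libraries and from 90.1 to 544.1 in the 8 STZ libraries. The antiproliferative gene Btg3 ran from 1.68 to 15.3, from 14.0 to 44.9 and from 7.17 to 64.6 CPM. In both genes the lowest STZ library was STZ SD replicate 1, which also had 119.5 CPM of H2-Ea-ps and 1.85 of Zfp97. STZ HFD replicate 1 had 120.8 CPM of H2-Ea-ps, 2.16 of Hist1h2bk, 8.73 of Ifi202b and 2.54 of Ifi44l, against at most 0.460, 0.511 and 0.145 of the last 3 in the other 7 STZ libraries. Ppy was at 12.5 CPM in DT HFD replicate 3 and 116.7 in replicate 2, against 4819 in replicate 1.

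Over the 10 untreated libraries Hbegf followed Ins2 (Pearson r = 0.78, permutation p = 0.00921, adjusted 0.00921; Spearman rho = 0.83, permutation p = 0.00476, adjusted 0.00635; r = 0.96 without the 2 libraries farthest from the median). It also followed the beta-cell score (r = 0.95, permutation p = 0.00016; rho = 0.93, permutation p = 0.00031; adjusted 0.00062 for both; r = 0.82 without the 2 farthest). These 2 relations were the family tested, with 100000 two-sided permutations each, and Ins2 lay at percentile 90.1 of all genes by its r with Hbegf.

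The library in no group had a log2 ratio of Hbegf to Ins2 of -7.21, 10.3 CPM of H2-Ea-ps and mitosis and lymphocyte scores of 4.48 and 6.21.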
